A study of Mus musculus with 8 samples.

How the data were processed

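Total RNA from the pancreas of 8 mice aged 1 week, 4 WT and 4 Glis3KO2, was labelled with Cy3 from 500 ng per sample, per the labels' protocols, and hybridised to Agilent whole mouse genome arrays with 1 channel. Groups and replicate numbers were taken from the sample titles. Per the file headers, the authors' scans were read with Agilent Feature Extraction 9.5.3.1, and the submitters' processing notes give version 9.5. The deposited values used here are spot intensity values on a linear scale from that software. Per the file headers, spatial and multiplicative detrending were on for the processed signal, and the background method is given as code 7. The processed signal is not scaled between arrays. Spot positions on the genome are those of build mm7, per the file headers. The deposited series table held, on every array, the same 45018 values as the processed signal, so its scale is linear and uncentred, and it was identical as an alternative. Dim spots had processed signals close to 0, so that log2 differences of dim probes depend on how background was removed.

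From these files, log2 of the processed signal minus each array's 75th percentile over 43379 non-control spots was computed. Spots flagged as non-uniform or population outliers, 56 to 130 per array, were left out, and the spots of a probe were averaged. No spot was saturated. A probe entered the test if it was well above background on at least 4 of the 8 arrays, whatever their genotype, and 33239 of 41174 probes did. Between 76.1% and 86.5% of probes were well above background per array. Scaling to the 75th percentile sets each array's bright probes level, so a change shared by most genes would not appear. Spike-in transcripts, 10 probes in all, had a median log2 difference of -0.27 between Glis3KO2 and WT arrays on this scale.

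Genotypes were compared with limma 3.58.1 (lmFit and eBayes, 2-sided) in R 4.3.3, with genotype as the sole term and Benjamini-Hochberg adjustment over all tested probes, at an adjusted p of 0.05. An adjusted p in the text comes from that fit unless another test is named. Of 25510 probes with a RefSeq accession, 22951 matched the reference gene table without versions, and 5141 probes took a newer symbol from it. Other probes kept the name in the array files. A gene was read from its brightest probe by mean over the 8 arrays. Where a probe is not well above background on any array of a group, the fold is given as a bound. On simulated data for this comparison, made from the means and residual spread of 33195 probes with 200 changed, the fit recovered 72% of the 2-fold changes and 99% of the 4-fold changes, and 5% of its calls were false. The simulated noise was normal and independent between probes, without the variation that probes of a real array share. These rates therefore need not hold for the real arrays.

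The comparison, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Of the probes past the threshold, well above background on all 4 arrays of the brighter group and with groups that did not overlap, the rule named the 10 with the largest increase and the 10 with the largest decrease, 1 per gene and with a gene symbol. It added up to 4 members past the threshold from each list, Glis3, and a fixed set of islet, duct and acinar genes. The pattern that tells symbols from IDs was corrected after values were seen, since names ending in Rik are symbols, which put B830017H08Rik in place of Galnt14 among the 10 largest decreases. Of the probes past the threshold, 2 carried an ID in place of a symbol. There were 23 tested lists, each with 1 probe per gene, which covered islet cell types, endocrine and acinar factors, duct, cilium, Hedgehog signalling, proliferation, stress, metabolic state and other cell types of the pancreas. A further list of sex-linked genes was read per array. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 23 lists. Lists of intestinal and motile cilium genes were added later for single tests.

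Alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median, no filter on dim probes, a filter on all 8 arrays, the deposited series table, the replicate number as a block, eBayes with trend and robust settings, array weights, and leaving out each array in turn. For lists they were camera with an estimated correlation, fry, and the mean of all probes of a gene. Xist level as a covariate, and leaving out Glis3KO2 replicates 3 and 4 together, which stood apart on the first principal component, were added after values were seen. Slide and scan could not serve as a block, because each held 1 genotype. Python 3.11.15 drew the figures.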

Results

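Whole pancreas was profiled from C57BL/6 mice aged 1 week that were either wild type (WT, 4 samples) or Glis3KO2 (4 samples), a line that the labels name as a Glis3 knockout without giving the deleted part. Glis3 is a zinc finger transcription factor related to the Gli proteins, and the series title places the comparison in the development and maturation of pancreatic beta cells, the insulin-secreting cells of the islets. Islets are a small part of the whole pancreas, most of which is acinar tissue that makes digestive enzymes. Each sample was hybridised to 1 single-colour array with 41174 distinct probes. Between 31353 and 35613 probes per array were well above background, and the unscaled 75th percentile of signal was between 460 and 693. The 4 arrays per genotype limit the precision of every value below. The labels do not say whether the pups of 1 genotype came from separate litters, so p-values measure the spread between these samples. All 4 WT arrays lay on 1 slide and all 4 Glis3KO2 arrays on another, so slide and genotype cannot be told apart in any comparison here. Xist, the transcript made from the inactive X chromosome of females, was high on 1 WT array and 3 Glis3KO2 arrays and low on the others, so the genotypes also differed in their mix of female and male pups.

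Glis3 itself was read by 1 probe, at positions 28054217 to 28057750 of chromosome 19 (mouse build mm7, as the array design gives it). It was well above background on 3 WT arrays and on 0 Glis3KO2 arrays. Its log2 signal relative to the array's 75th percentile was -6.06, -5.40, -5.49 and -5.34 on WT replicates 1 to 4 and -6.07, -6.43, -5.93 and -6.15 on Glis3KO2 replicates 1 to 4. The mean was -5.58 ± 0.33 (SD, n = 4) in WT and -6.15 ± 0.21 (SD, n = 4) in Glis3KO2, a difference not past the threshold (limma adjusted p = 0.496 over all probes). The probe was not well above background on any Glis3KO2 array. With lower signals there raised to that array's lowest among probes well above background, the WT mean was 1.11-fold higher. Since the difference was not past the threshold, that value is not a lower limit. WT replicate 1 fell within the Glis3KO2 range. The probe was too dim to enter the tested set, and a probe outside the deleted part checks nothing about the genotype.

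The 2 insulin genes were far lower in Glis3KO2 pancreas. Ins2 fell 13.0-fold (log2 difference -3.70, SE 0.22, adjusted p = 5.16e-04), from 8.97 ± 0.14 in WT to 5.27 ± 0.47 in Glis3KO2 (log2 relative to the 75th percentile, SD, n = 4 each, limma). Ins1 fell 5.82-fold (log2 difference -2.54, SE 0.19, adjusted p = 0.00130). The Ins2 probe lies at 139106050 to 139106109 of chromosome 7 and the Ins1 probe at 52166840 to 52166899 of chromosome 19 (mm7). A further Ins2 probe had a log2 difference of -3.36. Slc2a2, the glucose transporter of rodent beta cells, fell 4.77-fold, and Ucn3, a peptide of mature beta cells, fell 3.78-fold (log2 difference -1.92, and -1.18 with normexp background). Nkx6-1, a transcription factor of beta cells, fell 2.44-fold (log2 difference -1.28, SE 0.16), and G6pc2, an islet glucose-6-phosphatase, fell 2.18-fold (log2 difference -1.13, SE 0.15). The remaining beta cell genes past the threshold, named after their values were seen, were Slc30a8, a zinc transporter of insulin granules (log2 difference -1.48), Gjd2, a gap junction protein (-1.39), and Vdr, the vitamin D receptor (-1.36).

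Not every beta cell gene followed the insulin genes. Iapp, the hormone that beta cells package with insulin, had a log2 difference of 0.45 (SE 0.27, adjusted p = 0.688), with 6.82 ± 0.19 in WT and 7.27 ± 0.60 in Glis3KO2 (SD, n = 4 each, limma). Pdx1, a transcription factor needed for pancreas and beta cell identity, had a log2 difference of -0.06 (SE 0.11, adjusted p = 0.920), and Mafa, an activator of insulin transcription, -0.75 (SE 0.33, adjusted p = 0.550). Of the 24 beta cell genes fixed before the data were examined, 24 were tested, 9 fell, 0 rose and 15 did not pass the threshold over all probes. Adjusted over the list alone, 14 fell and 2 rose, the last being Pcsk1 and Prlr, named after their values were seen. The mean log2 difference of the list was -0.87 (camera adjusted p = 5.96e-14, preset correlation). With an estimated correlation the list's adjusted p = 0.247, and by fry, which tests only whether the list's own genes moved one way, adjusted p = 0.00559. No list kept its call with an estimated correlation.

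**Figure D1:**
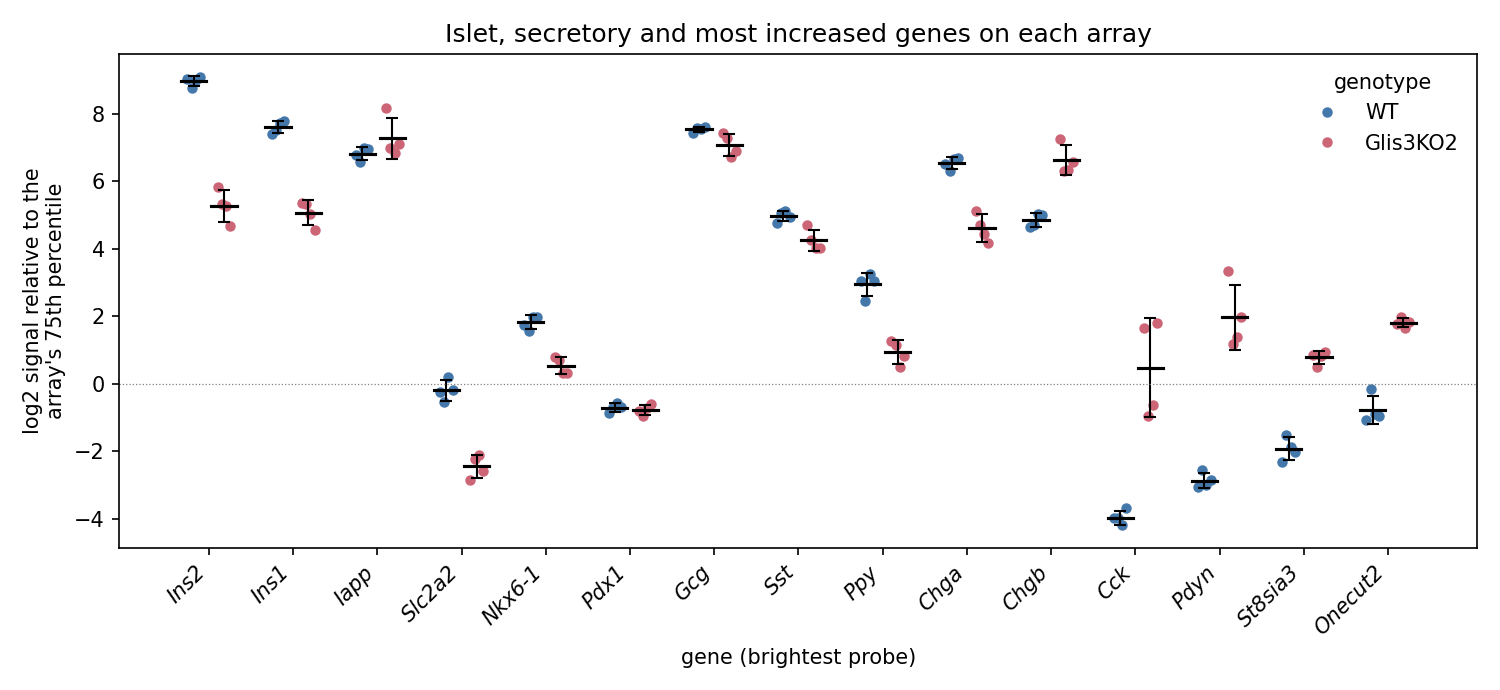
Log2 signal relative to each array's 75th percentile (vertical axis) for 15 genes (horizontal axis), with 1 point per array, WT in blue and Glis3KO2 in red, horizontal bars at the group mean and error bars of 1 SD (n = 4). Ins2 went from a mean of 8.97 to 5.27, while the groups overlap for Iapp and Pdx1, and Chgb, Cck, Pdyn, St8sia3 and Onecut2 were higher on every Glis3KO2 array than on any WT array.

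Other islet hormones moved less. Ppy, the pancreatic polypeptide of PP cells, fell 4.04-fold (log2 difference -2.01, SE 0.21, adjusted p = 0.00635). Gcg, the glucagon gene of alpha cells, had a log2 difference of -0.46 (SE 0.16, adjusted p = 0.442), Sst, the somatostatin gene of delta cells, -0.72 (SE 0.16, adjusted p = 0.196), and Ghrl, the ghrelin gene of epsilon cells, -0.73 (SE 0.13, adjusted p = 0.0786). Of the 12 genes of islet cells other than beta cells, 2 fell, Ppy and Irx2, a homeobox gene of alpha cells (log2 difference -0.88, SE 0.13, and -0.57 with normexp background, which ended the call with adjusted p = 0.0589), and 10 did not pass the threshold. A further pair of Irx2 probes, both dimmer, did not pass the threshold, with log2 differences of -0.87 and -0.04. Adjusted over the list alone, 6 of the 12 genes fell and 2 rose. The list's mean log2 difference was -0.42 (camera adjusted p = 7.76e-05). With an estimated correlation its adjusted p = 0.317, and by fry adjusted p = 0.0435. Without Glis3KO2 replicate 1, Sst passed the threshold (log2 difference -0.87, adjusted p = 0.0427), and Ghrl did with normexp background (-0.68, adjusted p = 0.0117) and with trend and robust eBayes (adjusted p = 0.0133).

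None of the 17 transcription factors of the endocrine lineage passed the threshold over all probes. Adjusted over the list alone, 7 fell and 0 rose, and the mean log2 difference was -0.40 (camera adjusted p = 7.76e-05). With an estimated correlation the adjusted p = 0.317, and by fry it was 0.0688. The mean without Glis3KO2 replicates 3 and 4 was -0.26. Neurod1, which acts downstream of Neurog3 in islet development, had a log2 difference of -1.38 (SE 0.26, adjusted p = 0.108), and passed the threshold with normexp background (-0.71, adjusted p = 0.0351) and with trend and robust eBayes (adjusted p = 0.0301). Neurog3, which marks endocrine progenitors, had a log2 difference of -0.09 (SE 0.13, adjusted p = 0.898).

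The chromogranins, proteins of endocrine secretory granules, moved in opposite directions. Chga fell 3.80-fold (log2 difference -1.93, SE 0.20, adjusted p = 0.00580) and Chgb rose 3.40-fold (log2 difference 1.77, SE 0.22, adjusted p = 0.0163). They were the only members past the threshold among 17 tested genes of the secretory machinery shared by endocrine cells. Adjusted over the list alone, 5 fell and 2 rose. The list's mean log2 difference was -0.14 (camera adjusted p = 0.0489). With an estimated correlation its adjusted p = 0.675, and without Glis3KO2 replicates 3 and 4 together its mean was 0.04 (adjusted p = 0.514). The call also ended without any 1 of WT replicates 2, 3 and 4 and Glis3KO2 replicates 2, 3 and 4, with means of -0.15 to -0.06 and adjusted p of 0.0576 to 0.155.

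The largest increases were in genes of neuropeptides. Pdyn, which encodes prodynorphin, rose 28.7-fold (log2 difference 4.84, SE 0.42, adjusted p = 0.00269), from -2.88 ± 0.22 in WT to 1.97 ± 0.97 in Glis3KO2 (SD, n = 4 each, limma). Cck, which encodes cholecystokinin, rose 21.7-fold (log2 difference 4.44, SE 0.61, adjusted p = 0.0282) and varied widely between the Glis3KO2 arrays, with log2 values of 1.65, -0.95, -0.63 and 1.81 on replicates 1 to 4. With normexp background the log2 differences were 4.05 for Pdyn and 3.099 for Cck. A dimmer Cck probe had a log2 difference of 0.27 and did not pass the threshold. St8sia3, a sialyltransferase, rose 6.53-fold (log2 difference 2.71, SE 0.18, adjusted p = 7.60e-04), and Onecut2, a homeobox transcription factor related to the duct and progenitor factor Onecut1, rose 5.97-fold (log2 difference 2.58, SE 0.19, adjusted p = 0.00138). Their probes start at 64660379 and 64774879 of chromosome 18 (mm7), 114.5 kb apart. Agt, which encodes angiotensinogen, rose 3.64-fold, and the developmental regulator Eya4 rose 3.06-fold (log2 difference 1.61, and 0.81 with normexp background). A further pair of Eya4 probes did not pass the threshold, with log2 differences of 1.18 and 0.36. The remaining genes among the 10 largest increases were 2210407C18Rik (log2 difference 2.07), Gm131 (log2 difference 1.88, and 0.94 with normexp background) and Pzp (log2 difference 1.62), which was well above background on only 2 WT arrays. With normexp background Pzp had a log2 difference of 0.31 and was not past the threshold (adjusted p = 0.602).

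The rule for named genes also took 4 genes outside the islet lists for their decrease, 3 of them by probes well above background on at most 1 Glis3KO2 array. Gad1, which encodes an enzyme of GABA synthesis, was lower in Glis3KO2 by its brightest probe, which was well above background on 4 WT arrays and 1 Glis3KO2 array, with a log2 difference of -2.73 that was -0.88 with normexp background (adjusted p = 0.0318). The gene named 3110079O15Rik fell 9.99-fold (log2 difference -3.32, SE 0.25, and -2.52 with normexp background). Slco1a6, an organic anion transporter, was at least 3.11-fold lower in Glis3KO2 (adjusted p = 0.0289), since its probe was not well above background on any Glis3KO2 array. This bound sets the WT mean against the mean of, on each Glis3KO2 array, the higher of the probe's own signal and the lowest signal among probes well above background. With normexp background it was not reached, with a log2 difference of -0.61, and the call ended (limma adjusted p = 0.128). The offset added there shrinks the differences of dim probes by itself, so that value does not test the bound. The probes of B830017H08Rik disagreed. One had a log2 difference of -6.91 (SE 0.67, adjusted p = 0.00508) and was well above background on 4 WT arrays and 1 Glis3KO2 array, with -3.18 under normexp background, while the gene's brightest probe had a log2 difference of 0.01 (adjusted p = 0.994).

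Acinar and duct genes differed little. Cpa1, a carboxypeptidase of acinar cells, had a log2 difference of -0.13 (SE 0.11, adjusted p = 0.792). None of the 25 tested digestive enzyme genes passed the threshold, over all probes or over the list alone, although 23 had a negative difference and the list's mean was -0.15 (camera adjusted p = 2.03e-04). With an estimated correlation the adjusted p = 0.530. With quantile normalization the mean was -0.01 and the list was no longer past the threshold. Of the 6 acinar transcription factors, 0 passed the threshold (list mean -0.15, camera adjusted p = 0.108). Among 14 duct genes 1 rose, Onecut2, and the list was not past the threshold (mean log2 difference 0.14, camera adjusted p = 0.574). Sox9, a factor of duct and progenitor cells, had a log2 difference of -0.38 (SE 0.13, adjusted p = 0.431). The 22 genes of the primary cilium and cystic kidney disease had a mean of -0.09 (camera adjusted p = 0.0843), with 0 members past the threshold over all probes and 1 lower over the list alone, Invs, named after its values were seen.

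**Figure D2:**
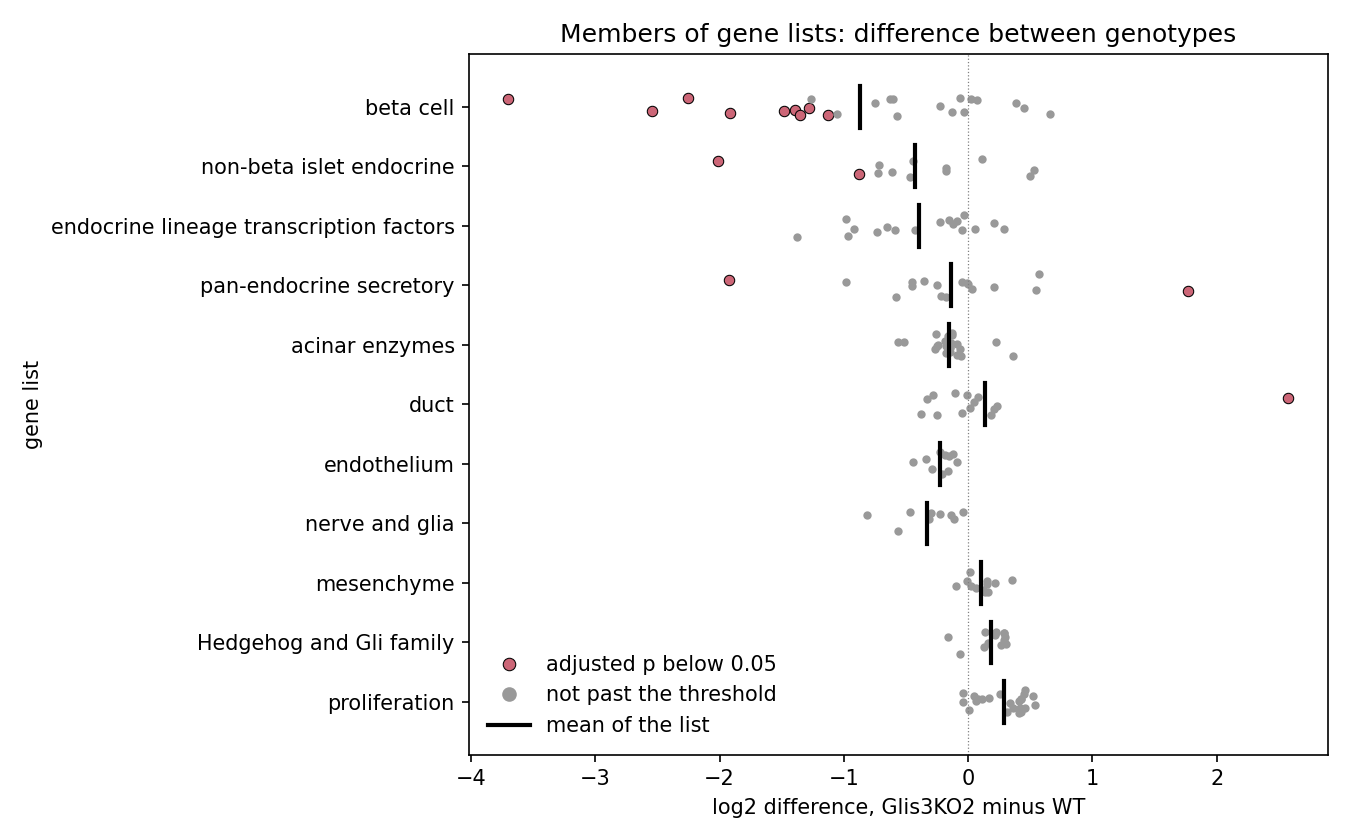
Log2 difference between Glis3KO2 and WT (horizontal axis) for each tested member of 11 gene lists (vertical axis), with 1 point per gene. Red points passed an adjusted p of 0.05 over all probes, and black bars mark list means, from -0.87 for the beta cell list to 0.29 for the proliferation list.

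Small shifts of many genes were seen in lists of dividing and supporting cells, with no member past the threshold over all probes in any of them. Spike-ins also differed between the slides. Of their 10 probes 9 were lower on the Glis3KO2 slide, with a median log2 difference of -0.27, against -0.009 for all tested probes. A shift that most spike-ins share does not measure how far the slides would move 1 list against other genes. Each genotype had its own slide, so the shifts of these lists cannot be told from a difference between the slides. Of 23 proliferation genes, 21 had a positive difference, with a mean of 0.29 (camera adjusted p = 5.33e-09). Adjusted over the list alone, 7 rose, among them the mitotic genes Ccnb1 (log2 difference 0.54) and Plk1 (0.42), named after their values were seen. With an estimated correlation the adjusted p = 0.447. Glis3KO2 replicates 3 and 4 stood apart from the other arrays on the first principal component (39.5 and 58.9, against -26.2 to 1.16). The list moved with it (correlation 0.933 over the 8 arrays). Other lists did so too, with -0.911 for nerve and glia, -0.878 for endothelium, -0.871 for non-beta islet and -0.792 for beta cell genes. The correlation was 0.606 for Hedgehog and Gli and -0.112 for mesenchyme. The WT arrays all lay below the Glis3KO2 arrays on that component, so a list that differs by genotype tends to follow it. Relative to the WT mean the proliferation list stood at 0.17, 0.01, 0.50 and 0.46 on Glis3KO2 replicates 1 to 4 and at -0.11 to 0.12 on the WT arrays. Without replicates 3 and 4 together, left out after seeing the data, its mean was 0.09 and not past the threshold (adjusted p = 0.364). The Hedgehog and Gli family list had a mean of 0.18 over 14 genes, 12 of them positive (camera adjusted p = 6.04e-04, and with an estimated correlation adjusted p = 0.317). The 10 endothelial genes were all lower, with a mean of -0.22 (camera adjusted p = 5.27e-04, and with an estimated correlation adjusted p = 0.447), and 2 fell over the list alone, Flt1 and Kdr. Their mean without Glis3KO2 replicates 3 and 4 was -0.10 and not past the threshold (adjusted p = 0.111). The 9 tested genes of nerve and glia were all lower, with a mean of -0.33 (camera adjusted p = 2.31e-04, and with an estimated correlation adjusted p = 0.317), and 1 fell over the list alone, the neurofilament gene Nefl. For nerve and glia that mean was -0.17 (adjusted p = 0.0182). Flt1, Kdr and Nefl were named after their values were seen. The 12 mesenchymal genes had a mean of 0.11 (camera adjusted p = 0.0388, and with an estimated correlation adjusted p = 0.675), a call that ended without any 1 of WT replicates 2 and 3 and Glis3KO2 replicates 1, 2 and 3, with means of 0.05 to 0.12 and adjusted p of 0.0572 to 0.314. The mesenchymal mean without Glis3KO2 replicates 3 and 4 together was 0.21 (camera adjusted p = 0.00456). The 9 tested glucose- and fasting-responsive genes had a mean of 0.28 (camera adjusted p = 0.00375, and with an estimated correlation adjusted p = 0.447), which without Glis3KO2 replicate 4 was 0.16 (adjusted p = 0.0566) and without replicates 3 and 4 was 0.23 (adjusted p = 0.0982). None of these 6 lists passed the threshold by fry. The other lists did not pass it by camera. Their mean log2 differences were -0.04 for the unfolded protein response, with a positive median of 0.04, 0.23 for acinar stress and acute phase genes, with a negative median of -0.02, -0.03 for immediate early genes, -0.08 for the circadian clock, -0.17 for the interferon response and 0.003 for leukocytes. They were -0.16 for adipocytes, 0.39 for erythroid cells and 0.06 for hepatocytes. Without 1 array the means of some of these lists turned direction, over -0.64 to 0.63 for adipocytes, -0.16 to 0.25 for leukocytes, -0.12 to 0.04 for the unfolded protein response, -0.07 to 0.01 for immediate early genes and -0.02 to 0.11 for hepatocytes, and with the Xist level in the fit that of the circadian clock was 0.02. The adipocyte mean without Glis3KO2 replicates 3 and 4 was 1.03 (adjusted p = 0.0226).

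Over all genes, 85 of 33239 tested probes passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 27 of them higher and 58 lower in Glis3KO2. They carried 78 distinct names, and 68 of the probes changed at least 2-fold, 25 up and 43 down. The number of calls rested on the arrays used. It was 35 without WT replicate 1, 35 without WT replicate 3, 36 without WT replicate 4, 39 without Glis3KO2 replicate 3 and 39 without Glis3KO2 replicate 4. With the Xist level in the fit, chosen after seeing the data, 31 probes passed the threshold, 30 of them among the 85. All 85 kept their direction with it, but groups that did not overlap could hardly turn in that fit. Without Glis3KO2 replicates 3 and 4, also chosen after seeing the data, 2 Glis3KO2 arrays remained and 11 probes passed the threshold, 9 of them among the 85. All 85 kept their direction in that fit, which was fixed in advance, since their groups did not overlap.

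Of the 23 named genes past the threshold, 12 stayed past it whichever array was left out: Ins1, Ins2, Slc2a2, Ppy, Chga, Pdyn, St8sia3, Onecut2, Eya4, 2210407C18Rik, 3110079O15Rik and the called probe of B830017H08Rik. The others lost the call in some of these fits, which could not turn their direction because their groups did not overlap. Ucn3 lost it without any of the 8 arrays (adjusted p 0.0565 to 0.175). Irx2 and G6pc2 lost it without any WT array or Glis3KO2 replicates 2, 3 or 4 (adjusted p up to 0.175 and 0.117). Cck and Chgb lost it without any WT array or Glis3KO2 replicate 4 (up to 0.130 and 0.0671). Gm131 lost it without any WT array or Glis3KO2 replicates 3 or 4 (up to 0.133), and Agt without any WT array or Glis3KO2 replicates 1 or 3 (up to 0.175). Nkx6-1 lost it without WT replicates 1, 3 or 4 or Glis3KO2 replicates 3 or 4 (up to 0.0776). Gad1 and Slco1a6 lost it without WT replicates 1, 3 or 4 or Glis3KO2 replicates 2, 3 or 4 (up to 0.0933 and 0.130), and Pzp without WT replicates 1, 3 or 4 or Glis3KO2 replicates 1, 3 or 4 (up to 0.140). With the replicate number as a block, Ins1, Ins2, Slc2a2, Pdyn, St8sia3, Onecut2 and 3110079O15Rik kept the call. The other named genes past the threshold lost it, with Ppy, Chga, Eya4, 2210407C18Rik and the called probe of B830017H08Rik among them. With no filter on dim probes, Cck, Gm131, Agt, Pzp, Gad1, Slco1a6, Ucn3, Irx2 and G6pc2 lost the call (adjusted p 0.0502 to 0.0853), and with trend and robust eBayes Cck did (0.0898). With the Xist level in the fit those 9 and Chgb, Ppy and Nkx6-1 lost it (0.0616 to 0.214). The fit without Glis3KO2 replicates 3 and 4 ended the call of 18 of the 23 (0.0504 to 0.282), and Ins1, Ins2, St8sia3, Agt and the called probe of B830017H08Rik stayed past the threshold.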

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

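The tests of the Xist level as a covariate and of chromosome 19 were chosen after results that bear on them were seen. In each genotype, named genes, list means, Glis3, Xist and array measures were searched for 1 array far from the other 3, in 122 groups of 4. The gap to the nearest array was divided by the group's range and set against Dixon's critical value for 4 samples. Chance flags about 1 in 20 groups, or 6.1 here, and 5 were found. Xist was highest on WT replicate 4, at 1.63 against -6.06 or lower on the other WT arrays (gap 0.911 of the range), and lowest on Glis3KO2 replicate 2, at -6.32 against 1.24 or higher (gap 0.969). Pzp was highest on WT replicate 2, at -5.09 against -5.84 (gap 0.887), and Ucn3 was lowest on Glis3KO2 replicate 4, at -4.32 against -3.37 (gap 0.832). The mean of the Hedgehog and Gli family list was highest on WT replicate 4, at -1.25 against -1.37 (gap 0.900).

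The number of genes that differ was weighed against chance, sex, slide and linked variants. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many probes past the threshold as the real 85, the real one itself, and the highest of the others gave 34. A split ranks first by chance 1 time in 35, so chance is unlikely for that count but cannot be excluded. The real split also separates the slides, so its rank is not particular to genotype. It ranked first as well for the 58 lower probes (1 of 35, highest other 29) and for the 68 changed at least 2-fold (1 of 35, highest other 33). It did not for the 27 higher probes, since 2 of 35 splits gave as many on their larger side, with 29 in the other. That other split set the arrays of high Xist against those of low Xist, and no further split called more than 2 probes. For gene lists, 1 of 35 splits gave the real 11 past the threshold, but the highest other gave 10, 8 splits with the real one among them gave 10 or more, and the median of the others was 5. The number of lists past the threshold is thus weak evidence.

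A different mix of female and male pups as the whole cause is argued against. Each genotype held arrays of high and of low Xist, and the groups of all 85 called probes did not overlap. With the Xist level in the fit, their log2 differences were 0.988 times those without it (median). In that fit 0% turned sign, and 31 probes passed the threshold. The signs decide little, because groups that did not overlap could hardly turn. Calls also favour probes with little spread within groups, which keeps the ratio high. Sex as part of the cause stays open for the called probes. Variants carried along with the knockout allele near Glis3 do not account for most of them by acting on genes of chromosome 19. Of the called probes 1.18% lay there, against 3.47% of the tested ones. The 1 called probe on that chromosome was that of Ins1. Effects of such variants on genes of other chromosomes were not tested. A difference between the slides stays open. Spike-ins differed between them by at most 0.43 in log2, against a median of 1.37 for the called probes, but each genotype had its own slide, and the 2 cannot be told apart.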

How the results depend on the processing

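The Xist level as a covariate and the fit without Glis3KO2 replicates 3 and 4 were chosen after seeing the data, and the other alternatives were fixed before. No named gene past the threshold changed direction, and all 85 called probes kept their direction wherever they were tested. The groups of all 85 did not overlap, so leaving out arrays could not have turned them. The replicate block, with 1 array of each genotype per number, could hardly move them either. The same holds for the Xist level, which was high and low on arrays of both genotypes. The counts of probes past the threshold moved by more than 1.5 times from 85 (27 higher, 58 lower, 68 at least 2-fold) as follows, and the cause was not tested except where stated. With no filter on dim probes 51 passed, 32 of them lower, among more probes tested. With trend and robust eBayes 143 passed, 45 higher and 98 lower. With normexp background 40 probes changed at least 2-fold. With Xist in the fit, with 1 residual degree of freedom fewer, 31 passed, 14 higher and 17 lower, 31 of them at least 2-fold. In the fit without Glis3KO2 replicates 3 and 4, with fewer samples, 11 passed, 5 higher and 6 lower, 11 of them at least 2-fold. Without 1 array, with fewer samples, 35 to 96 passed, 15 to 25 higher, 20 to 73 lower and 35 to 73 at least 2-fold. The deposited series table gave the same values and so tested nothing, Glis3 has 1 probe, and slide and scan blocks were not run because each held 1 genotype.

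Whether the replicate numbers pair the samples is not settled, and same-numbered arrays held the same position on their slides. Same-numbered arrays deviated from their group means with correlations of 0.13, 0.09, 0.24 and -0.04, against -0.20 to 0.14 for different numbers, and 3 of 4 WT arrays correlated best with their own number. With the replicate block 15 probes passed, 7 higher and 8 lower, all 15 at least 2-fold and among the 85. The mean of the pan-endocrine list was then -0.14 (adjusted p = 0.0841) and that of the mesenchyme list 0.11 (adjusted p = 0.0762). The block changed no other list's call.

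Of the 11 lists past the threshold by camera, none stayed past it with an estimated correlation, and beta cell (mean log2 difference -0.87) and non-beta islet genes (-0.42) alone did by fry. The means of the lists lost under both were -0.40 for endocrine lineage factors, -0.14 for pan-endocrine, -0.15 for acinar enzymes, 0.18 for Hedgehog and Gli, 0.29 for proliferation, 0.28 for glucose- and fasting-responsive, 0.11 for mesenchyme, -0.22 for endothelium and -0.33 for nerve. Pan-endocrine lost its call with normexp (-0.12) and with Xist (-0.17), mesenchyme with Xist (0.094), and acinar enzymes with quantile normalization (-0.013). Without Glis3KO2 replicates 3 and 4 the pan-endocrine mean turned to 0.037 and was not past the threshold, the adipocyte mean turned to 1.03 past it, proliferation (0.092), glucose- and fasting-responsive (0.23) and endothelium (-0.10) lost the call, and acinar factors (-0.20) gained one. Other gained calls were those of the cilium list with quantile normalization (-0.092) and the mean of all probes (-0.11), and of the interferon list with Xist (-0.33) and the mean of all probes (-0.24). Without 1 array, lists that gained or lost a call ranged over -0.25 to -0.065 (pan-endocrine), 0.050 to 0.17 (mesenchyme), 0.16 to 0.36 (glucose- and fasting-responsive), -0.20 to -0.10 (acinar factors), -0.12 to -0.065 (cilium), -0.17 to -0.020 (circadian clock), -0.29 to -0.0084 (interferon), -0.16 to 0.25 (leukocyte) and 0.12 to 0.66 (erythroid). Glis3 was not past the threshold under any alternative, and its probe was not well above background on any Glis3KO2 array. Of the 23 named genes past the threshold, 3 stayed past it under every alternative run, Ins1, Ins2 and St8sia3. Among values not past the threshold, Pdx1, Neurog3 and Cpa1 changed sign under 1 alternative each, and so did the means of some lists, the leukocyte list under 8 and the adipocyte list under 4 (-0.64 to 0.63 without 1 array). Signal over background limits what dim probes show. With normexp the log2 difference of Slco1a6 was -0.61, short of its bound of 3.11-fold, that of Gad1 -0.88 in place of -2.73, that of B830017H08Rik -3.18 in place of -6.91 and that of Pzp 0.31 in place of 1.62. Slco1a6, Pzp and Irx2 lost the call with it.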

Other observations

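Several changes past the threshold lay outside the lists, and the genes in this paragraph were chosen after their values were seen. Ren1, which encodes renin, rose 2.48-fold (log2 difference 1.31, SE 0.17, adjusted p = 0.0208, limma) in the same samples as its substrate gene Agt (3.64-fold). The Ren1 probe was dim, with a mean log2 signal of -4.58 in WT and -3.26 in Glis3KO2. Agt lost its call in 6 of the 8 fits without 1 array. Apart from Agt, the genes of this paragraph were not followed singly under the alternatives. Inhba, which encodes a subunit of activin, rose 2.59-fold (log2 difference 1.37, SE 0.12, adjusted p = 0.00281). Among the genes that fell were the growth factor receptor Fgfr3, by 2 probes (3.21-fold and 2.50-fold), the claudin Cldn2 (2.76-fold), the epithelial transcription factor Elf5 (2.81-fold), and Foxj1, which drives the formation of motile cilia (3.14-fold). Ces1d, a carboxylesterase, fell 3.77-fold, and Galnt14, which starts O-linked glycosylation, fell 3.77-fold.

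The test of Iapp against Ins2, for beta cells and for all islet cells, was chosen after both values were seen, and the other tests in this part were set before the values they measure were seen. The fall of beta cell genes may come from fewer beta cells, from lower expression within them, or from both, and the arrays of whole pancreas measure neither apart. A smaller share of beta cells, or of all islet cells, as the whole cause would lower Iapp and Ins2 alike, and is argued against by Iapp, whose log2 difference lay 4.15 above that of Ins2 (SE 0.22). The secretory genes that endocrine cells share do not decide it. Their median log2 difference was -0.17 (bootstrap SE 0.13) against -0.69 (bootstrap SE 0.31) for the beta cell list and -0.45 for the non-beta islet list, and the first gap, 0.51, was 1.6 times its SE once both errors were counted, which the bound first set for it had not done. A smaller share of beta or islet cells as part of the cause stays open.

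Pdyn, Cck and Chgb rose where Ins1, Ins2 and Chga fell. Intestinal tissue taken with the pancreas could bring Cck, but 9 detected intestinal genes of 12 had a median log2 difference of 0.11, 5 positive and 4 negative. Fabp2, abundant in gut, was not past the threshold (limma adjusted p = 0.802). The highest of them were the gut hormone genes Gip (log2 difference 0.79) and Sct (0.32), neither past the threshold and both named after their values were seen. Hormone-making gut cells were not tested apart. Nerve tissue could bring Pdyn and Chgb, but the median of the nerve and glia list was -0.30 (bootstrap SE 0.10). Which cells made these transcripts was not tested.

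St8sia3 and Onecut2, which rose 6.53-fold and 5.97-fold, are neighbours on chromosome 18, and the probe for the transcript C730009D12, 6.6 kb from the Onecut2 probe, rose 4.73-fold. A change over the whole neighbourhood could raise all of these. The 7 other tested genes within 1 Mb, C730009D12 included, had a median log2 difference of 0.026 (bootstrap SE 0.21), and C730009D12 was the only one past the threshold. Fech, Nars and Atp8b1, which lie close to Onecut2, had log2 differences of 0.04, 0.06 and -0.03. The rise was thus not seen across 1 Mb.

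Foxj1 could be lower because Glis3KO2 pancreas held fewer cells with motile cilia. The 21 detected genes of 26 in a motile cilium list had a median log2 difference of -0.13 (bootstrap SE 0.06), 14 of them negative and 0 past the threshold, while Foxj1 had a log2 difference of -1.65. A loss of such cells in proportion to Foxj1 was not seen.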
